A study of Drosophila melanogaster with 14 samples.

How the data were processed

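The data were RNA sequencing libraries from manually dissected heads of adult Drosophila melanogaster, 3 to 5 days old, kept at 25 degrees under 12 h of light and 12 h of dark and collected at zeitgeber time (ZT) 2, that is 2 h after lights on. Per the labels, each of the 14 libraries held RNA from 5 to 8 heads, was made from 200 ng of total RNA with a stranded mRNA kit, and came from flies with RNA interference (RNAi) against the gene Achilles (symbol Achl) or from control flies. The series design calls the replicates biological. There were 4 libraries in each male group and 3 in each female group. The control columns carry the name GFP and were matched to the control samples by sex and number; the genotype of the controls is not given in the sources used here.

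The deposited table held 1 value for each of 43329 transcript models in each library, in RPKM (reads per kilobase of model and M reads), with the position and length of each model. The unit is not named in the table and was read from the values: multiplied by the length of the model in kilobases, every low value fell on a whole multiple of 1 step per library, within 0.1 read, for values of up to 20.5 reads. The same step gave the number of reads per library, between 5.29 and 16.8 M (mega). The deposited values carry 4 decimals. A further scaling factor per library would leave the whole multiples intact, so they cannot show whether one was applied. The read numbers given here assume that none was. The submitters' notes name Bowtie and the genome build dm3; the versions, the counting tool and the strand setting of the counting are not given in the sources used here. The models of a gene carried nearly equal values, as when a read is counted whole for each model it overlaps. A read may therefore count for neighbouring genes that overlap, and for genes on the opposite strand if strand was not used. A second deposited table was identical (0 cells differed) and was not used.

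Each gene was represented by the model with the most reads, a choice made after the table was seen. Of the 14674 named genes, 7531 had 1 model. Names were brought to current symbols from the reference annotation, which is of another build and was used for names alone: 10467 genes matched by symbol, 2142 by annotation ID, 1579 by an older name, and 486 kept the name of the table. Positions are those of the table, in dm3. The 2376 models without a gene name and the 139 that span 2 genes were left out of the comparisons; the former were tested separately.

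The gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where a later choice is stated. The plan held a branch for counts and one for normalised values, and the second was used. Values were taken as log2(RPKM + 1), and the 9531 genes with a mean of at least 1 RPKM in at least 1 of the 4 groups were tested. A linear model with 1 mean per group was fitted to all 14 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend and robust settings, 10 residual degrees of freedom). The 5 contrasts were male RNAi against male control, female RNAi against female control, their average, their difference (the interaction of sex and RNAi), and male control against female control. A gene was called at a two-sided p adjusted by Benjamini-Hochberg under 0.05 over all genes tested. Fold changes are differences of mean log2(RPKM + 1) with their standard error (SE), so that those of genes near or under 1 RPKM are drawn towards 0. Levels are means ± standard deviation (SD) in RPKM. The level of Achl was also tested by an exact two-sided permutation test over all splits of the libraries, within each sex. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

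There were 26 gene lists with 813 entries (805 distinct genes): antimicrobial peptides; Bomanins and other immune-induced peptides; the Imd pathway and peptidoglycan recognition; the Toll pathway and its extracellular proteases; the JAK-STAT pathway and Turandot stress peptides; haemocyte and melanisation genes; core clock; clock output genes of the head; phototransduction and eye; neuronal; glial; neuropeptides; fat body and nutrient metabolism; muscle; gut; testis and accessory gland; ovary and eggshell; sex determination and dosage compensation; transgene markers and siRNA machinery; heat shock; detoxification and oxidative stress; ribosome biogenesis; cytosolic ribosomal proteins; mitochondrial respiratory chain; cuticle proteins; and odorant-binding and chemosensory genes. The 23 lists with at least 4 tested members were tested with limma's camera, which compares a list with the other genes, at a preset correlation between genes of 0.01 and with p adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Calls of members were also adjusted over the list alone.

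The genes named are the targeted gene; for each within-sex RNAi comparison and for the averaged one, the 10 rising and the 10 falling genes with the largest fold change among those called, with a mean of at least 1 RPKM in 1 group and every RNAi library on one side of every control library of the same sex; for each list up to 4 members with the smallest p in the averaged comparison and up to 2 in each within-sex one; and for the interaction and the sex difference the 5 with the smallest p in each direction. Other genes, such as PGRP-SC2, PGRP-SA, Amy-p, Amy-d, apolpp, Lsp2, Drsl5 and BomBc1, were named after their values were seen, where a short count asked for it.

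Other settings fixed beforehand were limma without the trend, libraries scaled to the same median, a scaling by trimmed means (TMM-type, 30% of the log ratios trimmed), no filter on low values, a minimum of 5 RPKM, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, only the 2 groups compared, and the other list tests. Added after the data were seen were limma's voom on the recovered reads with 0.5 read added, other choices of model per gene (highest mean RPKM, longest, mean over models), and the male libraries numbered 4 left out or given a term of their own. In counts simulated at these depths, with 67 genes changed 2-fold, the tests recovered 94.0% in the male, 76.1% in the female, 98.5% in the averaged, 37.3% in the interaction and 88.1% in the sex contrast, beside 7 to 19 other calls. At 1.5-fold the shares were 40.3%, 31.3%, 67.2%, 4.48% and 37.3%. The other calls are those of a whole run with all folds. In the female contrast, 19 unchanged genes were called beside 21, 51 and 66 genes changed 1.5-, 2- and 4-fold. That is more than the 0.05 that the threshold aims at. In the male contrast, 7 were called beside 27, 63 and 66. A list raised 1.5-fold passed in each of the 5 contrasts, and 0 of the 22 other lists passed. The simulated genes varied independently at 1 common dispersion (0.0238) and without a library that stands apart. These shares therefore do not cover genes with a wider spread. They also leave open false passes of lists whose genes move together, such as ribosomal protein genes (estimated correlation 0.70).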

Results

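RNA of Drosophila heads was sequenced to compare gene expression between flies with RNAi against Achilles (Achl) and control flies, in males and females, at ZT 2. The series title names Achilles as a gene under control of the circadian clock and as one that regulates innate immune function. The depth was 5.29 to 16.8 M reads in the 4 male RNAi libraries, 5.92 to 10.4 M in the 4 male controls. It was 5.56 to 8.90 M in the 3 female RNAi libraries and 7.26 to 11.9 M in the 3 female controls. One read in a transcript of 1 kilobase stood for 0.0595 to 0.189 RPKM, so that levels near these values rest on few reads. The 10 most abundant genes took 7.75% to 10.8% of the summed values in male libraries, 13.7% to 16.5% in female RNAi libraries and 19.1% to 20.6% in female controls. All levels below are mean RPKM ± SD and all log2 fold changes are given with their SE, with n = 4 libraries for a male group and n = 3 for a female group. Both male libraries numbered 4 stood apart: Dcr-2, an RNase of the small interfering RNA pathway, was at 62.5 RPKM in male RNAi 4 and 62.8 RPKM in male control 4, against 8.20 to 12.0 RPKM in the other 12 libraries.

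The level of the targeted gene shows how far its transcript was lower in whole heads with RNAi, not in single cell types. Achl (CG17386 in the table; dm3 chromosome 2R, 10307846 to 10312099, plus strand, 1 model) was at 19.95 ± 8.09 RPKM in male RNAi heads and 39.9 ± 10.2 RPKM in male control heads, 49.98% of the control level. In females it was at 21.8 ± 2.21 RPKM with RNAi and 33.5 ± 3.83 RPKM in controls, 65.2% of the control level. Every female RNAi library lay below every female control. In males, control 4 (24.7 RPKM) lay below RNAi 3 (26.7 RPKM), and RNAi 4 (8.20 RPKM) was the lowest library. The exact two-sided permutation test gave p = 0.0571 in males (70 splits), p = 0.1 in females, the smallest that 20 splits allow, and p = 0.00286 for the average of both sexes (1400 splits). In the test across all genes Achl was not called. The log2 fold change was -1.04 (SE 0.29, adjusted p = 0.116) in males, -0.59 (SE 0.33, adjusted p = 0.542) in females and -0.82 (SE 0.22, adjusted p = 0.137) on average. The difference between the sexes was -0.44 (SE 0.44, adjusted p = 0.715). Without both male libraries numbered 4, Achl passed in males (-0.89, adjusted p = 0.00122) and on average (-0.74, adjusted p = 0.000414). With the replicate block it passed in males (-1.04, adjusted p = 0.00205) and on average (-0.82, adjusted p = 0.00408). Without male control 4 it passed in males (-1.25, adjusted p = 0.0431) and on average (-0.92, adjusted p = 0.0429).

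**Figure D1:**
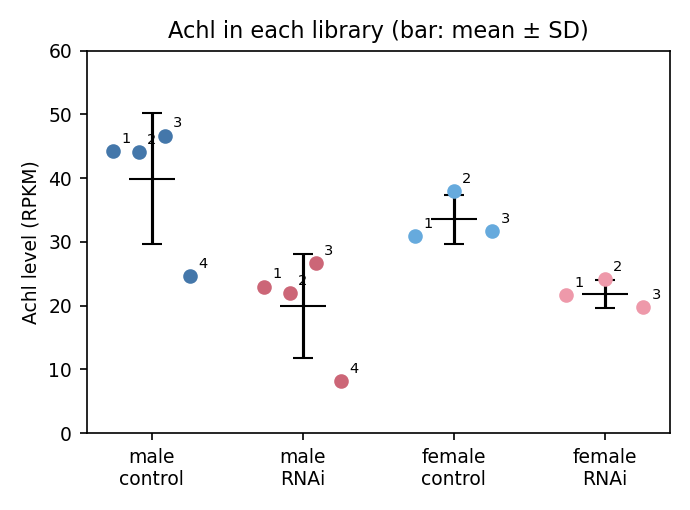
Level of Achl in RPKM (vertical axis, linear from 0) in each library of the 4 groups (horizontal axis). Points are libraries with their replicate number, and bars show the mean ± SD of 4 male or 3 female libraries per group. The male RNAi mean was 19.95 RPKM against 39.9 in male controls, and the female RNAi mean 21.8 against 33.5 in female controls; both male libraries numbered 4 lie below the others of their group.

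The male comparison asks which genes changed in male heads with Achl RNAi. Genes of the immune response rose by the largest folds. SPH93, a serine protease homologue (2L, 17454246 to 17456015), stood at 491 ± 265 RPKM with RNAi and 0.278 ± 0.293 RPKM in controls, a log2 fold change of 8.30 (SE 0.50, adjusted p = 2.05e-06). Drs, which encodes the antifungal peptide drosomycin (3L, 3369569 to 3369944), rose from 72.2 ± 130 to 4702 ± 2896 RPKM, a log2 fold change of 7.77 (SE 1.05, adjusted p = 0.00271). Dpt, which encodes the antibacterial peptide diptericin A, was at 3469 ± 2164 RPKM against 294 ± 579 RPKM in controls (7.22, SE 1.54, adjusted p = 0.0430). Of 9531 genes tested, 121 were called higher and 34 lower in male RNAi heads, and 101 of the 155 by at least 2-fold. The 10 rises with the largest folds also held CecA1, AttC, Dro, CecA2, DptB, Mtk and AttA, all genes of antimicrobial peptides, with log2 fold changes of 6.19 to 6.61.

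The genes that fell in male heads were at lower folds. Obp99b, an odorant-binding protein gene, fell from 132 ± 50.3 to 23.7 ± 14.8 RPKM (-2.66, SE 0.51, adjusted p = 0.0205). CG16926 (2R, 15387763 to 15389022) fell from 116 ± 14 to 28.2 ± 13.8 RPKM (-2.12, SE 0.28, adjusted p = 8.06e-04). Pepck, which encodes phosphoenolpyruvate carboxykinase of gluconeogenesis, fell from 639 ± 277 to 221 ± 44.2 RPKM (-1.44, SE 0.29, adjusted p = 0.0158). Est-Q, an esterase gene, fell from 46.2 ± 9.77 to 19.2 ± 1.62 RPKM (-1.20, SE 0.19, adjusted p = 0.00271). The other falls among the 10 largest were CG16995, phu, squ, IFT20 and Ugt37A3 (-1.78 to -1.14), with a mean of 7.08 RPKM or less in male heads. The last was mir-276aS, a model of 23 nucleotides listed at 0 in every male RNAi library, for which no fold is given.

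Among the gene lists, antimicrobial peptides rose in male heads. Of these, 12 of 17 tested members rose over all genes (13 adjusted over the list alone) and 0 fell. The median log2 fold change was 6.19 (camera adjusted p = 1.81e-25; adjusted p = 0.0464 with an estimated correlation). In 13 of the 17, every RNAi library lay above every control, where chance gives 1.43% for a single gene, but these genes move together (estimated correlation 0.54). Male control 2 held high levels of the same peptides, with Dpt at 1163 RPKM against a mean of 4.06 RPKM in the other male controls and CecA1 at 84.7 against 0.862 to 1.78 RPKM. The Bomanins and other short peptides induced on infection rose as well, 11 of 18 over all genes (adjusted over the list alone 13 rose and 1, Nplp2, fell). Their median was 2.69 (camera adjusted p = 3.98e-22; adjusted p = 0.0464 with an estimated correlation). BomS1 went from 152 ± 49.0 to 2759 ± 537 RPKM (4.20, SE 0.24, adjusted p = 1.86e-07) and BomS3 from 192 ± 32.9 to 2170 ± 343 RPKM (3.49, SE 0.26, adjusted p = 2.05e-06). In the Imd pathway, which senses bacterial peptidoglycan, 5 of 23 members rose (6 adjusted over the list alone). These were PGRP-SC2 (5.24), PGRP-SB1 (3.06), PGRP-LB (1.04) and PGRP-LF (0.76), of the peptidoglycan recognition protein family, and the transcription factor Rel (1.28). The list had a median of 0.08, camera adjusted p = 0.00114 and adjusted p = 0.485 with an estimated correlation. In the Toll pathway 5 of 24 rose (8 adjusted over the list alone), namely PGRP-SD (3.13), PGRP-SA (1.49), the proteases Hayan (1.5) and SPE (1.15), and Spn42Dd (0.90). Its median was 0.26, with camera adjusted p = 8.10e-06 and adjusted p = 0.485 with an estimated correlation. The haemocyte and melanisation list passed upwards with a median of 0.18 (camera adjusted p = 0.0184; adjusted p = 0.485 with an estimated correlation). Of 22 members NimB1 (1.49) and NimC1 (0.70), both of phagocytosis, were called over all genes and over the list alone. The heat shock list passed upwards with 0 of 18 members called (1, Hsp68, over the list alone; median 0.16, camera adjusted p = 0.0184; adjusted p = 0.548 with an estimated correlation).

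The fat body and nutrient list passed downwards in male heads, with a median of -0.39 (camera adjusted p = 8.10e-06; adjusted p = 0.475 with an estimated correlation). Of 27 members 3 fell (Obp99b, Pepck and the lipophorin gene apolpp, -0.73) and 2 rose (the amylase genes Amy-p, 2.10, and Amy-d, 1.63); adjusted over the list alone 8 fell and 3 rose. Further lists that passed downwards were detoxification (44 members, median -0.08, camera adjusted p = 0.00278), clock output (20 members, -0.03, 0.0353), neuropeptides (28 members, -0.12, 0.0353) and glial genes (20 members, -0.04, 0.0406). For the first 3 of these adjusted p = 0.485 with an estimated correlation, and for glial genes adjusted p = 0.586 with an estimated correlation. In these 4 lists 0 members were called over all genes, and over the list alone 1 detoxification gene fell. The other 12 tested lists had adjusted p of 0.198 to 0.940. None of the 19 core clock genes, 37 phototransduction genes, 31 neuronal genes, 80 ribosomal protein genes, 59 respiratory chain genes, 23 muscle genes, 18 sex determination genes or 12 transgene and siRNA genes was called by limma in males, over all genes or over the list alone. Beside this, 842 of all genes had an unadjusted p under 0.05 and voom made 151 calls in all. Tep2 rose among 13 JAK-STAT and stress peptide genes (0.99; over the list alone 1 rose and 1 fell). Polr1H fell among 39 ribosome biogenesis genes (-0.66), Cpr72Ec rose among 12 cuticle genes (0.87), and Obp56h rose (0.95) and Obp57a fell (-0.70) among 41 odorant-binding and chemosensory genes. The direction of camera, which is relative to other genes, was opposite to the small median of 6 lists, none of which passed: phototransduction, neuronal, ribosome biogenesis, ribosomal protein, respiratory chain and odorant-binding genes. Gut genes had 0 members tested, testis 1 (janB, -0.66, adjusted p = 0.390) and ovary 2, none called over all genes in any RNAi comparison. Over the list alone, where janB stands by itself, janB was lower in males and for the interaction.

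**Figure D2:**
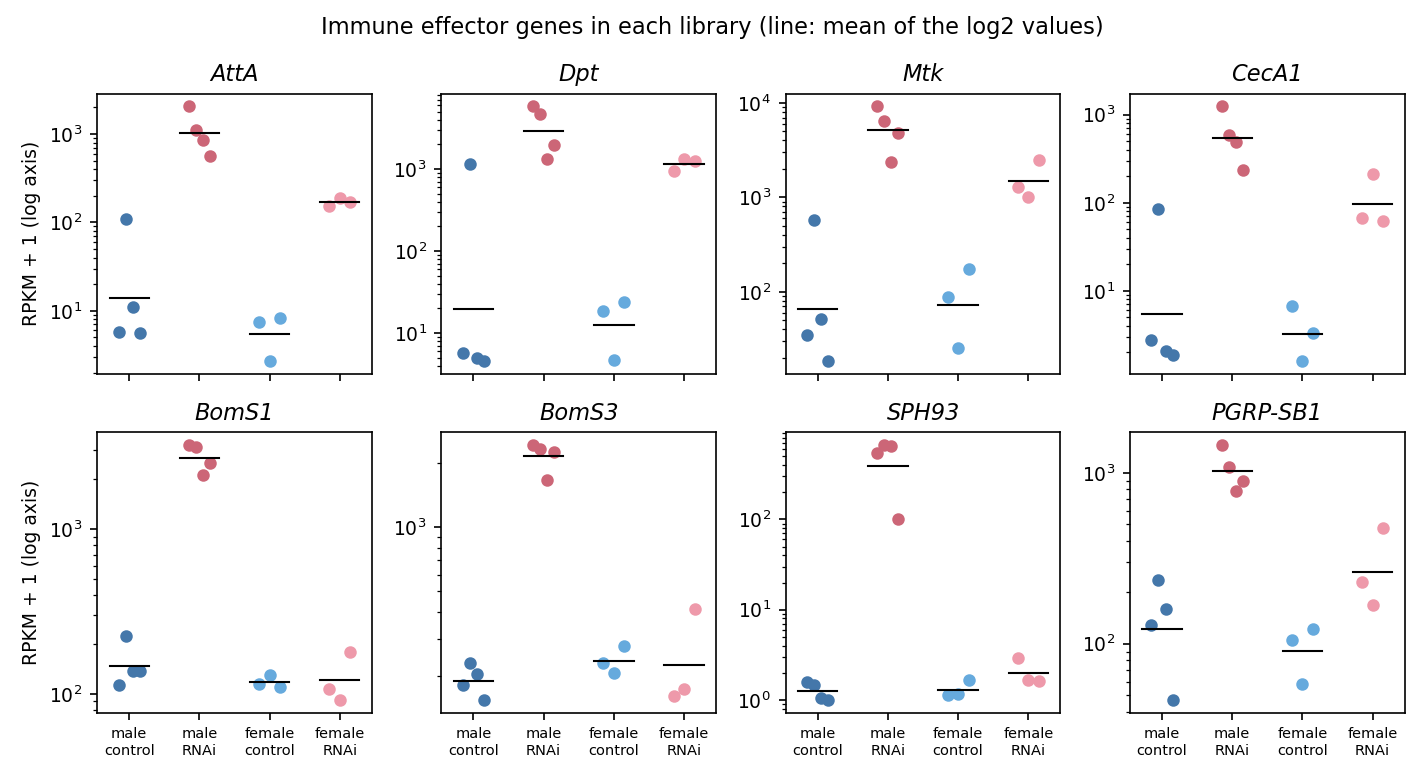
Level of 8 immune genes as RPKM + 1 (vertical axes, logarithmic, scaled per gene) in each library of the 4 groups (horizontal axes); points are libraries and lines the mean of the log2 values. In BomS1, BomS3 and SPH93 the male RNAi libraries lie above all others. In AttA, Dpt, Mtk and CecA1 the RNAi libraries of both sexes lie above the controls of their sex, and male control 2 is the high control, with Dpt at 1163 RPKM.

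Of the 35 named calls in males, 20 held with each of the 14 libraries left out in turn, among them SPH93, Drs, AttA, AttC, CecA2, Mtk, BomS1, BomS3, Rel, CG16926 and Est-Q, while the number of calls was 92 without male RNAi 1; the call of Dpt held in 1 of the 14, the fit without male control 2 (adjusted p up to 0.154), those of Cpr72Ec in 2 (0.168), Polr1H and Obp57a in 3 (0.118 and 0.178) and mir-276aS in 4 (0.140), that of Dro ended without 8 libraries (up to 0.119), those of phu without 6 (0.0983), DptB without 5 (0.0827), IFT20 and Obp56h without 4 (0.0971 and 0.102), Obp99b without 3 (0.0784), SPE without 2 (0.0603) and Ugt37A3 without 1 (0.0549), that of CecA1 without male RNAi 1 or male control 1 (up to 0.0540) and that of Pepck without male RNAi 2 or male control 3 (up to 0.0596). With the replicate block the calls of Dpt, Ugt37A3, IFT20, Polr1H, Cpr72Ec and mir-276aS ended. The lists that kept passing with each library left out were antimicrobial peptides, Bomanins, Imd, Toll and fat body, and detoxification ended without male control 2 alone (0.0622), but the clock output, neuropeptide, glial, haemocyte and heat shock lists each ended without 2 to 5 of the male libraries. When libraries were scaled to the same median or by trimmed means, 105 and 113 genes were higher and 60 and 57 lower.

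The female comparison asks the same of female heads. Few genes were called, and among those called Cyp4d21 had the largest rise. Cyp4d21, a cytochrome P450 gene of the head fat body (2L, 7605579 to 7607714), was at 18.8 ± 4.46 RPKM with RNAi and 1.34 ± 0.413 RPKM in controls (log2 fold change 3.07, SE 0.23, adjusted p = 1.28e-05). Fad2, a desaturase of female pheromone synthesis, was at 12.5 ± 4.59 against 2.33 ± 1.65 RPKM (2.12, SE 0.34, adjusted p = 0.0290) and was listed at 0 in every male library. The fatty acid elongase genes eloF (1.80, SE 0.25) and CG16904 (1.48, SE 0.21) rose from 0.460 ± 0.415 to 4.16 ± 1.57 and from 0.153 ± 0.0384 to 2.28 ± 0.793 RPKM, both with adjusted p = 0.00888. Of 9531 genes, 6 were called higher and 2 lower, all by at least 2-fold; 900 had an unadjusted p under 0.05. The other rises were CG30083 (1.47, SE 0.22, adjusted p = 0.0173), a serine protease gene, and the chaperone gene Hsp70Bb (1.45, SE 0.20, adjusted p = 0.00888). The 2 falls were arg, which encodes arginase (-1.13, SE 0.20, adjusted p = 0.0443), and the cuticle protein gene Cpr51A (-1.10, SE 0.18, adjusted p = 0.0336).

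Antimicrobial peptides passed upwards as a list in female heads, with a median of 3.5 over 17 members (camera adjusted p = 6.42e-09; adjusted p = 0.638 with an estimated correlation). No member was called over all genes by limma, which made 8 calls in all against 7 by voom, but adjusted over the list alone 11 rose and 1, Drsl5, fell (-0.71). Every RNAi library lay above every control in 13 of the 17 and below every control in 2. Chance gives 5% in each direction for a single gene, but these genes move together (estimated correlation 0.54). Dpt was at 1175 ± 203 RPKM with RNAi and 14.6 ± 9.87 RPKM in controls (6.52, SE 1.78, adjusted p = 0.403). AttA was at 169 ± 19.2 against 5.16 ± 3.05 RPKM (4.94, SE 0.97, adjusted p = 0.182). When only the female libraries were fitted 6 of these peptides were called, and without male control 2 in the shared fit 10 were. The Imd pathway list passed upwards with 0 of 23 members called over all genes or over the list alone (median 0.16, camera adjusted p = 0.0291; adjusted p = 0.638 with an estimated correlation). Bomanins did not pass, with 0 of 18 called, a median of -0.06, a mean of 0.03 and camera adjusted p = 0.544; nor did the Toll list (24 members, median -0.19, camera adjusted p = 0.0737).

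The list of 80 ribosomal protein genes passed downwards in female heads, with a median of -0.53 (camera adjusted p = 7.22e-13; adjusted p = 0.638 with an estimated correlation). So did the list of 59 respiratory chain genes, with -0.45 (camera adjusted p = 2.93e-19; adjusted p = 0.638 with an estimated correlation). No member of either list was called over all genes or over the list alone by limma. Every RNAi library lay below every control in 49 of the 80 and in 44 of the 59, where chance gives 5% for a single gene. The genes of each list move together (estimated correlation 0.70 and 0.65), so 1 chance order of the libraries can part many of them at once. Muscle genes (23 members, median -0.18) and odorant-binding genes (41 members, -0.15) passed downwards as lists, each with camera adjusted p = 0.0106 (adjusted p = 0.775 and 0.638 with an estimated correlation). Neuronal genes (31 members, 0.24) and ribosome biogenesis genes (39 members, 0.15) passed upwards as lists, each with camera adjusted p = 0.0106 (adjusted p = 0.775 and 0.638 with an estimated correlation). In these 4 lists 0 members were called over all genes, with 3 ribosome biogenesis genes higher over the list alone. Fold changes went with transcript length in females (Spearman rho across genes 0.221), and the lists differ in length. Against genes outside the lists matched on length and level, a median of -0.36 was left for ribosomal protein genes. It was -0.43 for respiratory chain and 0.08 for neuronal genes. The difference of library means left was -0.33, -0.40 and 0.08 in this order. Its exact permutation p was 0.2, 0.2 and 0.5 over 20 splits, where 0.1 is the smallest. Cyp4d21 was the member called in both the clock output list (over the list alone 1 rose and 1 fell) and the sex determination list, and Hsp70Bb in the heat shock list (2 over the list alone). The other 15 lists had adjusted p of 0.0676 to 0.863; in 5 of them (Bomanins, JAK-STAT, glial, heat shock and detoxification) the median or mean differed in sign from the direction of camera.

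The call of Cyp4d21 held with each of the 14 libraries left out, and the 7 others ended without female RNAi 2 or 3 or without female control 2 or 3, in each of which 1 gene was called; 19 genes were called without male control 2, 18 without both male libraries numbered 4, 35 when only the female libraries were fitted, and 3 with the replicate block, with a pseudocount of 0.1 or with a minimum of 5 RPKM. The Imd, muscle, neuronal, ribosome biogenesis and odorant-binding lists each ended without 1 to 3 of the female libraries (camera adjusted p up to 0.505, for neuronal genes without female control 1).

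**Figure D3:**
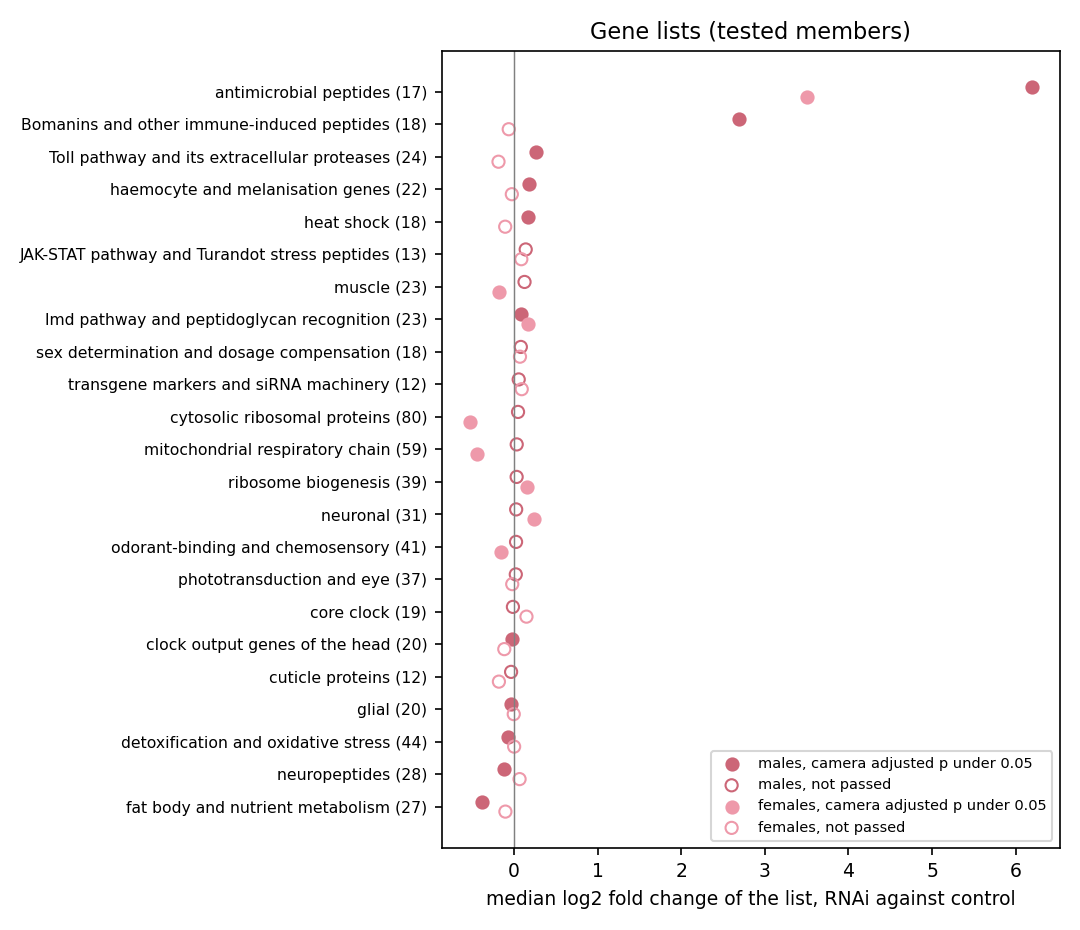
Median log2 fold change of RNAi against control (horizontal axis) of the tested members of 23 gene lists (vertical axis, number of members in brackets), in males and females; filled circles mark lists with a camera adjusted p under 0.05, which is relative to other genes. Antimicrobial peptides stand at 6.19 in males and 3.5 in females, Bomanins at 2.69 and -0.06, and ribosomal protein genes at 0.05 and -0.53.

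The averaged comparison gives the mean of the male and female effects, which a change in 1 sex alone can also move. Dpt rose most (6.87, SE 1.17, adjusted p = 0.0182), followed by Dro (6.05, SE 1.0), CecA1 (5.74, SE 0.86), DptB (5.68, SE 0.91) and AttA (5.57, SE 0.64, adjusted p = 0.00134). Cyp4d21 (1.71, SE 0.15, adjusted p = 5.68e-05), CG30083 (1.18, SE 0.15, adjusted p = 7.07e-04) and Hsp70Bb (0.93, SE 0.13, adjusted p = 0.00217) rose as well, where Cyp4d21 differed between the sexes (interaction -2.73). CG16995, which fell most, was at 0.245 ± 0.235 against 3.73 ± 2.77 RPKM in males and 0.0936 ± 0.162 against 1.59 ± 0.237 RPKM in females (-1.51, SE 0.22, adjusted p = 0.00264). Cpr51A (-0.78), the cytochrome P450 gene Cyp6t1 (-0.77), CG3513 (-0.76) and yellow-e (-0.55) were lower in every RNAi library than in every control of the same sex. In all, 72 genes were called higher and 7 lower of 9531.

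Of 17 antimicrobial peptides 12 rose on average (13 adjusted over the list alone), with a median of 4.71 (camera adjusted p = 2.45e-23; adjusted p = 0.115 with an estimated correlation). Of 18 Bomanins and related peptides, of which 0 were called in females, 8 rose on average (13 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 1.37e-13; adjusted p = 0.193 with an estimated correlation). Of 23 Imd genes 4 rose (7 adjusted over the list alone; camera adjusted p = 1.35e-04; adjusted p = 0.440 with an estimated correlation), namely PGRP-SB1, Rel, PGRP-LB and PGRP-LF. Ribosome biogenesis genes passed upwards (0 called, 2 over the list alone, camera adjusted p = 0.0456; adjusted p = 0.600 with an estimated correlation). The lists that passed downwards were respiratory chain (median -0.23, camera adjusted p = 7.77e-14; adjusted p = 0.440 with an estimated correlation), ribosomal protein (-0.23, 5.90e-11; adjusted p = 0.578 with an estimated correlation), fat body (-0.21, 1.35e-04; adjusted p = 0.440 with an estimated correlation), detoxification (-0.08, 0.00218; adjusted p = 0.478 with an estimated correlation). The others were clock output (-0.11, 0.00837), odorant-binding (-0.02, 0.0169) and cuticle genes (-0.15, 0.0350), each with adjusted p = 0.440 with an estimated correlation. Of these 7 lists, members called were Cyp4d21, which rose in the clock output list, and Obp56h, which rose (0.80). Over the list alone 3 fat body, 2 clock output, 1 detoxification and 2 odorant-binding genes were lower, and 1 clock output, 2 detoxification and 3 odorant-binding genes higher. The other 12 lists had adjusted p of 0.0996 to 0.848. Of these, 1 member was higher in each of the Toll (2 over the list alone), JAK-STAT, haemocyte (2 over the list alone), sex determination and heat shock lists (2 over the list alone). Core clock, phototransduction and neuropeptide genes had a median or mean of opposite sign to camera. The 19 core clock genes held 0 calls in each of the 4 RNAi comparisons, over all genes or over the list alone, by limma; tim, a core clock gene, had 0.32 (SE 0.13, adjusted p = 0.428) on average.

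The call of CG3513 ended without 9 of the 14 libraries and that of yellow-e without 11 (adjusted p up to 0.122 and 0.131), those of PGRP-LF without 11, PGRP-LB and PGRP-SD without 9 and Rel and Obp56h without 7 (up to 0.127, 0.117, 0.0870, 0.0861 and 0.0896), and those of Dpt without 5, Drs without 4 and Dro without 1 (up to 0.0604, 0.0588 and 0.0545), whereas PGRP-SB1, CG16995, Cpr51A, Cyp6t1, AttA, CecA1, DptB, Cyp4d21 and Hsp70Bb held without each; 152 genes were called without male control 4 and 175 without both male libraries numbered 4. The replicate block ended the calls of CG3513 and yellow-e. Libraries scaled to the same median gave 67 higher and 46 lower genes and the scaling by trimmed means 70 and 44, with the cuticle list lost under both (camera adjusted p = 0.161 and 0.138) and the odorant-binding and ribosome biogenesis lists under the first (0.0555 and 0.0502), and these 3 lists ended without 7, 3 and 6 of the libraries.

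The interaction asks whether the RNAi effect differed between males and females. The effect on BomS1, a Bomanin gene, was higher in males than in females by 4.16 (SE 0.36, adjusted p = 7.72e-05), with 125 ± 46.6 RPKM in female RNAi and 117 ± 9.82 RPKM in female control heads. The same held for BomBc3 (3.81, SE 0.40, adjusted p = 2.61e-04), BomS3 (3.55, SE 0.39, adjusted p = 3.18e-04) and BomS2 (3.33, SE 0.47, adjusted p = 0.00331). The neighbouring protease homologue genes SPH93 (7.69, SE 0.76, adjusted p = 3.18e-04) and CG18563 (4.52, SE 0.47, adjusted p = 2.61e-04) had larger effects in males. So did the protease gene CG11842 (2.05, SE 0.21, adjusted p = 2.61e-04), with every female RNAi library below every control. Cyp4d21 (-2.73, SE 0.31, adjusted p = 3.18e-04), CG16926 (-2.46, SE 0.43, adjusted p = 0.0214) and eloF (-1.76, SE 0.33, adjusted p = 0.0329) had effects that were higher in females. In all, 23 genes had a higher and 3 a lower effect in males.

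Of 18 Bomanins and related peptides 7 were called for the interaction (12 adjusted over the list alone), and 14 were higher and 4 lower, with a median of 2.29 (camera adjusted p = 1.60e-15; adjusted p = 0.250 with an estimated correlation; fry adjusted p = 0.0130). Antimicrobial peptides had a median of 1.73 with 0 of 17 called (1, Drs, over the list alone; camera adjusted p = 5.61e-05), the Toll list 0.47 with 0 of 24 called (6 over the list alone; 1.47e-05). Haemocyte genes had 0.26 (0 of 22, 1 over the list alone; 0.00318), respiratory chain genes 0.51 (0 of 59; 1.96e-09), ribosomal protein genes 0.60 (0 of 80; 2.26e-05) and muscle genes 0.38 (0 of 23; 0.00496). Neuronal genes had -0.22 (0 of 31; camera adjusted p = 0.0176), fat body genes -0.32 (0 of 27, over the list alone 2 higher and 1 lower; 0.0381) and ribosome biogenesis genes -0.10 (0 of 39, 1 lower over the list alone; 0.0381). For each of these 9 lists adjusted p = 0.693 with an estimated correlation. The other 13 lists had adjusted p of 0.120 to 0.896, with Cyp4d21 the 1 member called in the clock output and sex determination lists, and the JAK-STAT and clock output lists had a median and mean of different sign. Across all 9531 genes the male and female log2 fold changes correlated with Pearson r = 0.23 (0.10 to 0.34 with 1 library left out). Those left-out fits gave r an SE of 0.23 (jackknife), as large as r itself. Spearman rho was -0.13, and genes are not independent replicates. Of the same sign in females were 98 of the 155 genes called in males. CG30083 alone was called in both sexes in the same direction, against 0.0762 genes expected higher in both by chance and 0.00713 lower in both (0 found).

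The interaction calls of BomS1, BomS3, BomBc3, CG18563, CG11842 and Cyp4d21 held without each of the 14 libraries (CG18563 ended under voom), that of CG16926 ended without 7 and that of eloF without 9 (adjusted p up to 0.0875 and 0.152), and the number of calls was 16 without female control 3, 17 without female RNAi 2, 43 without male RNAi 4, 53 without both male libraries numbered 4 and 48 with the replicate block. The replicate block ended the call of eloF. The neuronal list ended without male control 4, female RNAi 1 or female control 1 (camera adjusted p up to 0.433), the muscle list without male RNAi 4, male control 1 or male control 3 (up to 0.109), and the fat body and ribosome biogenesis lists each without 7 libraries.

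**Figure D4:**
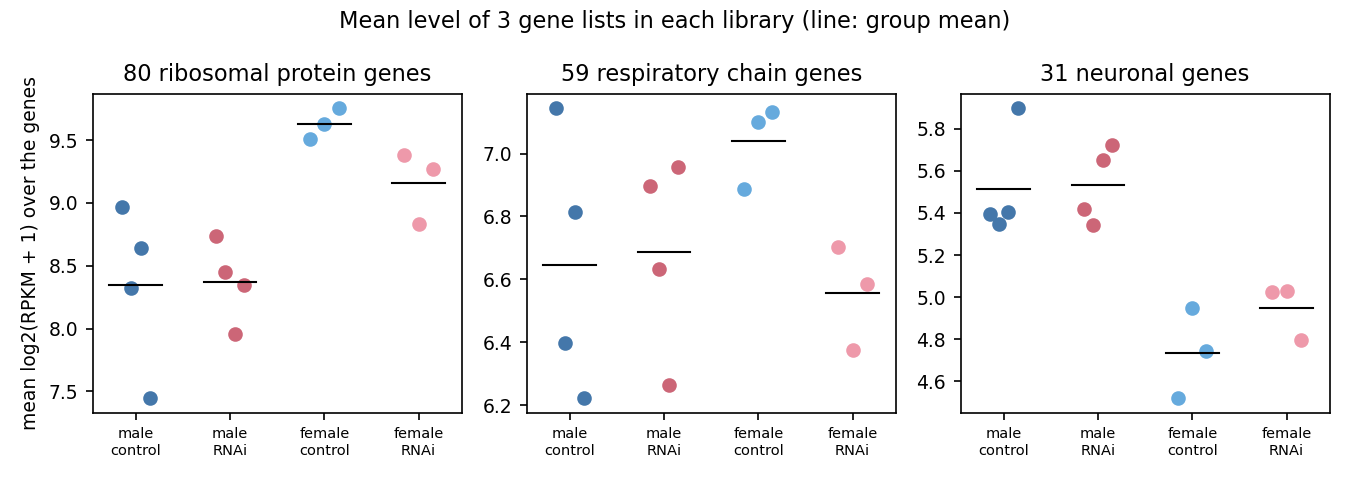
Mean log2(RPKM + 1) over 80 ribosomal protein, 59 respiratory chain and 31 neuronal genes (vertical axes, not starting at 0) in each library of the 4 groups (horizontal axes); points are libraries and lines group means. Ribosomal protein genes lie at 9.51 to 9.76 in female controls and 7.45 to 8.97 in male controls, and respiratory chain genes spread from 6.22 to 7.15 among male controls.

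The comparison of male with female control heads gives the sex difference without RNAi and checks the labels. The yolk protein genes Yp2 (1.35 ± 1.37 RPKM in males, 15984 ± 1967 in females) and Yp3 (10.8 ± 6.52 against 13949 ± 1940) were lower in males by -12.88 (SE 0.49, adjusted p = 2.86e-09) and -10.41 (SE 0.44, adjusted p = 2.39e-09). The male dosage compensation RNAs lncRNA:roX1 (443 ± 72.4 against 2.06 ± 0.307 RPKM; 7.17, SE 0.16, adjusted p = 3.10e-13) and lncRNA:roX2 (44.2 ± 9.86 against 0.0478 ± 0.0419 RPKM; 5.41, SE 0.15, adjusted p = 4.41e-12) were higher. Cyp4d21 (5.63, SE 0.22), Cyp313a1 (2.90, SE 0.22) and sxe2, a lipase gene (2.23, SE 0.20), were higher in males, and Obp99a (-7.23, SE 0.30), arg (-3.66, SE 0.18) and Obp56e (-3.61, SE 0.18) lower. Of 9531 genes, 1802 were called higher and 598 lower in males, 355 of the 2400 by at least 2-fold, where the median of all genes was 0.14.

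Of 80 ribosomal protein genes 76 were lower in males (78 adjusted over the list alone), with a median of -1.33 (camera adjusted p = 1.21e-40; adjusted p = 0.501 with an estimated correlation). Of 31 neuronal genes 25 were higher (27 adjusted over the list alone; median 0.83, camera adjusted p = 5.31e-09; adjusted p = 0.501 with an estimated correlation). Higher too were 7 of 20 glial genes (9 over the list alone; 0.33, 0.0106; adjusted p = 0.693 with an estimated correlation). Fold changes went with transcript length here too (Spearman rho 0.355). Against genes matched on length and level, a median of -1.24 was left for ribosomal protein, -0.25 for respiratory chain and 0.39 for neuronal genes. The difference of library means left was -1.06, -0.25 and 0.42 in this order. Its exact permutation p was 0.0286, 0.257 and 0.0286, with 0.0286 the smallest of 35 splits. The respiratory chain list passed downwards with a median of -0.41 (1 of 59 called, 0 over the list alone; camera adjusted p = 7.15e-10; adjusted p = 0.700 with an estimated correlation). Haemocyte genes (5 of 22 lower, median -0.21), fat body genes (8 lower and 4 higher of 27; 10 and 5 over the list alone; median -0.04, mean -1.34) and ribosome biogenesis genes (8 lower and 2 higher of 39; -0.14) passed downwards as lists, each with camera adjusted p = 1.72e-04 and adjusted p = 0.501 with an estimated correlation. The Toll list passed downwards (1 of 24 lower; -0.25, camera adjusted p = 0.0182; adjusted p = 0.791 with an estimated correlation). The other 15 lists had adjusted p of 0.0818 to 0.933. Of these, 7 of 19 core clock genes were higher (8 over the list alone), among them tim (1.23, SE 0.19, adjusted p = 8.44e-04). Beside 1802 higher and 598 lower of all 9531 genes, 10 of 44 detoxification genes were higher and 0 lower, 8 and 1 of 37 phototransduction and 8 and 1 of 28 neuropeptide genes. Higher and lower were 8 and 7 of 41 odorant-binding, 6 and 6 of 18 sex determination, 3 and 5 of 20 clock output and 3 and 1 of 18 heat shock genes. The antimicrobial peptides, Bomanins, clock output, sex determination and cuticle genes had a median or mean of opposite sign to camera.

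All 10 genes named for the sex difference held without each library, but scaling changed the balance: with libraries at the same median 942 genes were higher and 1086 lower, by trimmed means 867 and 1116, and the median of all genes went from 0.14 to 0.01 and 0.00. The count was 1442 without female control 1 and 1389 without female control 3, and the Toll list ended without male control 4 (camera adjusted p = 0.0607).

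Several of the values named stand on reads that other genes may share. AttA and AttB, CecA1 and CecA2, Amy-p and Amy-d, Hsp70Bb and its copies, and the Bomanins are similar in sequence. Since the strand setting of the counting is not given, reads of CG5050 opposite SPH93 and CG18563, of CG4744 opposite AttC, of CG15120 opposite CG16926, of CG33214 opposite Est-Q, and of elav and CG4293 opposite arg may be counted with them. The same holds for reads of Asx and CG30197 opposite Cpr51A, of CG5778 opposite BomBc3, of PGRP-SB2 opposite PGRP-SB1, of nimB2 opposite NimB1, of Rpn6 opposite AttB, of CG10395 opposite IFT20, of Pde6 opposite Cyp313a1 and of Mhcl opposite sxe2. On the same strand, eloF overlaps CG8534, CG3513 overlaps Acp24A4, SPE overlaps CG18754, Rel overlaps Nmdmc and squ overlaps grp.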

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

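The tests of the Bomanin pattern and of male control 2 and the splits that part every replicate number were chosen only after the result was seen, while the tests of the ribosomal protein genes and the other counts over splits of the libraries were set before.

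In 28 of 301 groups of 4 male libraries, 1 library lay apart from the other 3 by more than Dixon's 95% critical value. Chance gives about 1 in 20 groups, and 11 of the 28 were in male control 4. For genes, the gap and the range were taken on log2(RPKM + 1), not on the RPKM printed. Among immune genes, SPH93 was at 101 RPKM in male RNAi 4 against 549 to 669 RPKM (gap 0.895 of the range) and CG18563 at 15.9 against 47.5 to 57.3 RPKM (0.851). BomT2 was at 473 RPKM in male RNAi 3 against 655 to 699 RPKM (0.832). In male RNAi 1, Tep2 was at 218 against 147 to 151 RPKM (0.931), Tep1 at 13.7 against 0.144 to 0.351 RPKM (0.935) and NimC1 at 15.3 against 18.2 to 18.6 RPKM (0.880). In male control 2, Dpt was at 1163 RPKM against a mean of 4.06 RPKM (0.955), CecA1 at 84.7 against 0.862 to 1.78 RPKM (0.895), CecA2 at 36.7 against 0.213 to 0.425 RPKM (0.953), and edin, an immune-induced gene, at 30.2 RPKM while listed at 0 in the other 3 (1).

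Male control 4 and male RNAi 4 stood apart in Achl, at 24.7 against 44.1 to 46.7 RPKM (gap 0.910 of the range) and 8.20 against 22 to 26.7 RPKM (0.831), and in Dcr-2, at 62.8 and 62.5 RPKM (0.884 and 0.948). In male control 4 the neuronal genes unc-13 (163 against 92.8 to 102 RPKM, 0.839), futsch (39.5 against 25.9 to 27.5 RPKM, 0.863) and Shab (34.9 against 20.6 to 21.2 RPKM, 0.939) were higher. The detoxification gene Cyp6a20 was higher (74.2 against 27.9 to 30.1 RPKM, 0.922) and Cyp6a8 lower (71.4 against 106 to 110 RPKM, 0.913). Est-Q (31.6 against 50.7 to 51.8 RPKM, 0.958), NimC1 (7.82 against 11.1 to 11.8 RPKM, 0.858) and dsx, of sex determination (4.20 against 4.85 to 4.97 RPKM, 0.855), were lower. The 10 most abundant genes took 8.87% of the values in male control 4, the lowest share of the male controls (0.841). Outside these 2 libraries, phu was at 2.57 RPKM in male RNAi 1 against 1.33 to 1.5 RPKM (0.836) and at 3.82 RPKM in male control 1 against 7.94 to 8.63 RPKM (0.892). CG3513 was at 5.84 RPKM in male RNAi 3 against 8.40 to 9 RPKM (0.837), lncRNA:roX1 at 541 RPKM in male RNAi 3 against 407 to 420 RPKM (0.894), and male control 1 had fewer reads than the other male controls (0.867).

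For 10 named genes the RNAi effect differed between males and females in a test of the difference itself: SPH93 (7.69), CG18563 (4.52), BomS1 (4.16), BomBc3 (3.81), BomS3 (3.55), BomS2 (3.33), CG11842 (2.05), Cyp4d21 (-2.73), CG16926 (-2.46) and eloF (-1.76), as log2 fold change in males minus that in females. Among the transcript models without a gene name, which the comparisons do not use, 15 of 734 tested were called in males, 13 higher and 2 lower.

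Of 18 Bomanins and related peptides 11 rose in male RNAi heads and 0 were called in female RNAi heads, and 7 were called for the interaction. The list had a median interaction of 2.29, with 14 members higher and 4 lower and adjusted p = 0.250 with an estimated correlation. Without both male libraries numbered 4, which stand apart, the median interaction was 2.03 and 14 of the 18 members were higher, against those libraries as the whole cause. More fat body or blood cells in the male RNAi heads, as the whole cause, would raise the genes of those tissues by as much as the Bomanins. The fat body list had a median of -0.39 and the haemocyte list 0.18 (quartiles 0.03 to 0.39) against 2.69 for the Bomanins. A smaller change in these tissues is not excluded. The haemocyte list passed upwards (camera adjusted p = 0.0184), and fat body members were called both ways (3 fell and 2 rose), so that list does not measure the amount of tissue alone. Whether the knockdown was weaker in females cannot be told apart from an equal one, since the interaction of Achl was -0.44 with an SE of 0.44, and a biological difference between the sexes stays open, untested.

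Antimicrobial peptides were high in male control 2, with Mtk at 581 RPKM and AttA at 109 RPKM against means of 34.2 and 6.44 RPKM in the other male controls. If RNA at the mean levels of the 4 male RNAi libraries had been mixed in, 1 share would account for all genes that RNAi raised. The antimicrobial peptides needed a median of 12.0% of such RNA (quartiles 9.45% to 14.5%, 12 members). The Bomanins needed 3.62% (1.77% to 7.97%, 11 members), which argues against a mix at these mean levels. Single members overlapped, with 5.55% for the antimicrobial peptide gene Drs and 20.3% for BomT2. The peptides varied widely among the male RNAi libraries (Dro 1481 ± 1276 RPKM). A single library as the source was not tested, so mixing is not excluded. Achl was at 44.1 RPKM in male control 2, above every male RNAi library, which argues against a swapped or wrong label. No biological explanation is given by the design, and none was tested.

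Ribosomal protein genes were lower in male than in female control heads, by a median of -1.33. Against genes outside the list matched on transcript length and level, a median of -1.24 was left, against length and level as the whole cause. The difference of library means left was -1.06 (exact permutation p = 0.0286, the smallest of 35 splits). A few genes take more of the reads in female controls, but under TMM-type scaling, which removes such a shift, the median was -1.49. Sex as a biological difference stays open and was not tested apart from the design.

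Other splits of the libraries were compared with the real ones, the real one counted among them. For the male comparison 2 of 35 splits called at least as many genes as the real 155, so chance cannot be excluded by this count: controls 1 and 3 with RNAi 1 and 4, set against the other 4, gave 369, which points to a structure of the samples. That split keeps the libraries numbered 1 on one side and those numbered 2 on the other. Of the 8 splits that part the RNAi and control library of every number, as the real one does, the highest other gave 2 genes, but 8 splits are too few for a share under 0.05. With the replicate block, 136 genes were called in males. For the number of lists passing in males (11), 8 of 35 splits gave as many (highest other 15). For females, the 10 splits are too few for a share under 0.05: 1 split, the real one, gave 8 genes (highest other 1), and 3 gave as many lists as the real 8 (highest other 13). Averaged over the sexes, 1 of 100 splits drawn from 700, the real one, called as many as 79 genes (highest other 36). This bears on the number of calls and not on each gene, and a structure of the samples is not excluded. For the 11 lists chance cannot be excluded (5 of 100, highest other 13). For the interaction, 2 of 100 splits gave at least the real 26 genes, with a highest other of 79, the real male split with the female labels exchanged. The real male split with a mixed female one gave 23. Exchanging the female labels turns the contrast into the sum of the male and female effects, that is the averaged comparison with its 79 calls. Both of these splits keep the male effect whole. Splits that mix RNAi and control libraries within a sex weaken the RNAi effect itself, so the count does not test whether the sexes differ. For its 10 lists, 20 of 100 splits gave as many (highest other 13). For the sex difference, 1 of 35 splits, the real one, called as many as 2400 genes (highest other 1344), which again bears on the number of calls. As many lists as the real 8 passed in 18 of 35 splits (highest other 12).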

How the results depend on the processing

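The choice of voom, of other models per gene and of leaving out or modelling the male libraries numbered 4 was made only after the data were seen, and all other settings before.

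Achl was lower in every setting run, and its call depended on the male libraries numbered 4: it passed without both (-0.89 in males, -0.74 on average), with a term for them (-1.04 and -0.82) and with the replicate block (-1.04 and -0.82). With single libraries left out its log2 fold change was -1.25 to -0.68 in males, -0.67 to -0.50 in females, -0.92 to -0.64 on average and -0.65 to -0.09 for the interaction. The residuals of the RNAi and control libraries of 1 number correlated at 0.31, 0.38, 0.01 and 0.32 in males, where RNAi 1, 2 and 4 matched the control of their own number best, and at -0.25, 0.01 and 0.14 in females, where RNAi 3 did. Whether male libraries of 1 number were handled together is not given in the sources used here.

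With single libraries left out, the number of genes called was 92 to 172 in males (92 without male RNAi 1), 1 to 19 in females (1 without female RNAi 2 or 3 or female control 2 or 3, and 19 without male control 2), 54 to 152 on average (152 without male control 4), 16 to 43 for the interaction (43 without male RNAi 4, 17 without female RNAi 2, 16 without female control 3) and 1389 to 2461 for the sex difference (1389 without female control 3, 1442 without female control 1). The number of lists passing was 6 to 14 in males, 5 to 14 in females, 9 to 14 on average, 7 to 12 for the interaction and 8 to 10 for the sex difference. The correlation of male and female effects was 0.10 to 0.34, with a jackknife SE of 0.23.

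When only the 2 groups compared were fitted, 76 genes were called in males and 35 in females. Female calls were 3 with a minimum of 5 RPKM, 3 with a pseudocount of 0.1, 3 with the replicate block, 18 without both male libraries numbered 4 and 11 with a term for them. Averaged calls were 175 without both and 125 with the term. Interaction calls were 48 with the replicate block, 53 without both and 60 with the term. By voom the counts were 151, 7, 89, 30 and 2567, and by limma without trend 148, 8, 79, 28 and 2346. In the remaining settings for these counts the number stayed within 1.5 times.

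With an estimated correlation, 2 lists passed in males (antimicrobial peptides and Bomanins) and 0 in females, on average, for the interaction and for the sex difference. By fry 2 lists passed in males, 0 in females, 4 on average, 1 for the interaction and 11 for the sex difference. Directions turned, with a pass in the other setting, for 3 lists that had not passed: respiratory chain genes in males without male RNAi 3 (0.18, range -0.10 to 0.21 with single libraries left out), neuronal genes in males without male control 4 (0.15, range -0.042 to 0.15), and sex determination genes in the sex difference by fry (-1.13).

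Of the named genes called, 2207 comparisons of a gene under another setting kept the call and 319 lost it. Of those not called, 4042 stayed so, 77 passed and 4 changed sign without a call. For lists that had passed, 881 kept and 167 lost the pass. Of those that had not, 1303 stayed so and 63 passed in the same direction. A further 90 turned direction without passing, and 3 turned direction and passed.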

Other observations

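The tests of Dcr-2 and of the models without a gene name were chosen only after the result was seen.

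Of 734 transcript models without a gene name, 13 were called higher and 2 lower in male heads, beside 155 of 9531 named genes called, and no test linked them to the immune genes. A model at 2R 14268884 to 14269428 on the minus strand, beside BomBc1 and BomS1, was at 155 RPKM with RNAi and 10.9 RPKM in controls (log2 fold change 3.79, adjusted p = 4.10e-05). A model between CecA2 and CecB (3R, 26038556 to 26038891) was at 3.60 against 0.162 RPKM (1.96). MIP07065 (2R, 10526066 to 10526280) was at 739 against 63.0 RPKM in males and 125 against 16.6 RPKM in females (4.66 and 2.79, adjusted p = 0.00751 in males). MIP09718 (3R, 13470409 to 13470981) was at 16.4 against 0.601 RPKM in males and 14.8 against 0.533 RPKM in females (3.09 and 3.11, averaged adjusted p = 0.00603). At 2L 5620759 to 5623811, 5 overlapping models had 2.60 to 3.14 in males. The 2 that fell were nc_7373.a, at 5.76 against 15.8 RPKM (-1.35), and a model at 2R 15522606 to 15523416, listed at 0 in the male RNAi libraries and at 1.90 RPKM in male controls.

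Dcr-2 overlaps Rab4 on the opposite strand, and Rab4 was at 49.0 to 74.8 RPKM in all 14 libraries, so the 62.5 and 62.8 RPKM of Dcr-2 in both male libraries numbered 4 were not shared by its neighbour.

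The female RNAi heads may be shifted towards the male pattern of expression over many genes, but the called genes went both ways: Cyp4d21 (3.07) rose and arg (-1.13) fell towards the male level, while Fad2, listed at 0 in males, rose (2.12) away from it. The genes eloF and CG16904, at 0.0237 and 0.0375 RPKM in male controls, also rose in females, away from the male level. Hsp70Bb rose towards it, from 0.744 to 3.83 RPKM against 5.82 RPKM in male controls. The remaining calls went in the male direction and past that level. CG30083 rose from 6.88 to 20.8 RPKM (male controls 11.6 RPKM) and Cpr51A fell from 3.84 to 1.25 RPKM (male controls 2.09 RPKM). Across 9531 genes the female RNAi effect correlated with the averaged difference between the sexes at r = 0.147 after the trend with transcript length was removed (0.178 before), a test set before the result was seen. With the sex difference of the controls r was 0.364, but the female controls enter both sides of that value. The averaged difference holds all 4 groups, so both female groups enter it too, and genes that RNAi raised in both sexes can add to its r. Of 26 genes over 4-fold higher in males on average, 16 were higher with RNAi in females (median 0.23). Of 26 over 4-fold higher in females, 16 were lower (median -0.16). The median of all genes in this comparison was 0.045. Both sets were picked by the averaged difference, so genes that RNAi raised in males can enter the first without a sex difference in controls. SPH93, with an interaction of 7.69, was at 0.278 RPKM in male and 0.321 RPKM in female controls. These counts therefore do not test a shift. The male transcript lncRNA:roX1 was at 3.09 ± 0.689 RPKM in female RNAi and 2.06 ± 0.307 RPKM in female control heads (0.41, adjusted p = 0.517).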
